A study of Mus musculus with 4 samples.

How the data were processed

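RNA from the left lung lobe of 4 newborn mice at postnatal day 1, 2 RykSL/SL and 2 wild type, was made into libraries with a stranded poly(A) mRNA kit (TruSeq Stranded mRNA) from 3 micrograms of total RNA each, per the labels' protocols. The labels give the number of mice per genotype, so the libraries are separate animals; they give neither sex nor litter. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, the tools used were FastQC, STAR 2.4.0a, featureCounts 1.5.1 of the Subread package and DESeq2 1.14.1, with the builds mm10 and GRCm38. The strand setting and the treatment of reads with several alignments are not given in the sources used here.

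The deposited table has 48709 genes with coordinates, biotype and annotation terms. Its values, treated here as a score, are whole numbers that the authors deposited under a name that marks them as normalized counts; how they were scaled is not given in the sources used here, and the values themselves, described next, are those of scaled and rounded counts, not raw counts. All values were whole, the library totals were 19516482, 19987634, 18743098 and 18658239 (mutant replicates 1 and 2, wild-type replicates 1 and 2), and the median ratio of each library to the geometric mean lay between 1.0005 and 1.0049. In mutant replicate 2 no gene had a value of 3, 10 or 17, as happens when whole counts are multiplied by a factor above 1 and rounded. Fitting that pattern gave factors of 0.855, 1.1722, 0.9866 and 0.994 and estimated count totals over genes of about 22830000, 17050000, 19000000 and 18770000. Reads given to several copies of a gene, described below, would enter these totals more than once. Simulated tables with known factors were recovered within 0.02% in 6 runs. With factors below 1, neighbouring counts fall on the same value, so the counts themselves were not recovered and no count model was run. The depth does not limit the larger values, but a value under about 10 rests on a few reads, and the values of single lungs carry counting error as well as differences between mice. Of the gene identifiers, 48349 were found in GENCODE release M21 (GRCm38), all on the same chromosome, and 44016 with the same start. Coordinates are those of the deposited table, counted from 1.

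Copies of a gene appear to have been given the same reads: a nuclear pseudogene of the mitochondrial gene mt-Co3 stood at 100.1% of that gene's value in every library. For the 125 genes selected for naming, the share of 50-base sequences of the GENCODE transcripts found in transcripts of other genes, on either strand, was therefore computed. It was above 10% for 14 genes and above 50% for 3. Besides genes flagged below, those above 10% included Notum (29.5%), Etv5 (24.5%), Nefm (18.6%), Dbp (16.2%), Gja5 (15.3%), Cebpd (13.7%) and Glul (12.6%). Exons of another gene on the same strand overlapped by at least 100 bases in Notch2, and exons on the opposite strand in 22 of the genes, where reads cannot be assigned with certainty because the strand setting is not known.

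The test of single genes was limma 3.58.1 (R 4.3.3, with the data.table package, version 1.17.8) with an empirical Bayes mean-variance trend on log2(value + 1), two-sided, over the 18436 genes with a mean of at least 10 over the 4 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are mutant minus wild type on the log2(value + 1) scale, which understates changes of low genes. The moderated variance had 4.07 prior degrees of freedom. Gene lists for lung cell types, WNT, planar cell polarity and NOTCH genes, immune cells, other tissues that dissection could carry along, proliferation, stress and RNA quality were written before the data were examined, as were the tests and the alternatives. The 39 lists with at least 5 measured genes were tested with limma's camera with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. Annotation terms with 10 to 300 measured genes were tested in the same way; 345 of the 6843 terms could not be paired with a name. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

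Named genes were set by a rule. Ryk was always named. In each direction the 14 genes with the largest absolute log2 fold change were named among those called, with a mean of at least 50 and both mutant libraries beyond both wild-type libraries, leaving out predicted gene models, pseudogenes, haemoglobin genes, Xist and Y-linked genes. Of every list that passed in camera, and of the goblet, club cell, canonical WNT target and NOTCH lists, up to 4 members with the smallest p were named. Some items that these rules select are not reported here. Other genes are said to have been named after their values were seen. On simulated counts for this comparison, with 2 libraries per genotype, 18430 to 18466 genes tested and 200 genes changed in each of 3 runs, 76.7% of genes changed 2-fold and 99.3% of genes changed 4-fold were called; 1.12% of calls were false. None of 30 unchanged lists was called, and the shifted list was called in all 3 runs. The simulation gave every gene and library the same dispersion (0.0145) and drew genes independently of each other. In the real data the mutant lungs differed more from each other than the wild-type lungs did, and genes can vary together. These rates therefore need not hold for the real libraries.

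The alternatives were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, rescaling by trimmed mean of M values (TMM, trimming 30% and 5%) and by median of ratios, quantile normalization, no trend, the replicate number as a block, and each library left out in turn. Protein-coding genes alone were added as an alternative after the data were seen. With 2 against 2 libraries no outlier test applies.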

Results

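RNA was sequenced from the left lung lobe of newborn C57BL/6 mice at postnatal day 1, from 2 mice with the SL allele on both copies of Ryk (RykSL/SL, called mutant here) and from 2 wild-type mice. Ryk encodes a single-pass receptor for WNT ligands with a kinase-like domain. The comparison asks which genes differ in the newborn lung between these genotypes. Each library is a separate mouse, as the extraction protocol describes. The normalized values summed to 19516482 and 19987634 in mutant replicates 1 and 2 and to 18743098 and 18658239 in wild-type replicates 1 and 2. The rounding of the values gave estimated count totals over genes, before scaling, of about 22830000, 17050000, 19000000 and 18770000 in the same order. The wild-type lungs were close to each other, with an SD of 0.314 for the log2 difference over genes. The mutant lungs differed more from each other, with an SD of 0.60. Mutant replicate 1 was about as far from wild-type replicates 1 and 2 (0.61 and 0.575) as from the other mutant lung, and mutant replicate 2 stood furthest from the wild type (0.757 and 0.744).

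Ryk itself (ENSMUSG00000032547, chromosome 9, positions 102834917 to 102908305, GRCm38) had normalized read counts of 2757 and 2203 in the mutant lungs and 2528 and 2525 in the wild-type lungs. The log2 fold change was -0.04 with a standard error of 0.16 (limma, adjusted p = 0.926), so the amount of Ryk transcript did not differ beyond the replicate spread. Without mutant replicate 2 it was 0.126. The labels do not say what the SL allele does to the transcript, and gene totals cannot tell the alleles apart. Mutant replicate 1 differed from the other 3 lungs in sex-linked genes. It had 24836 normalized counts of Xist, the RNA that coats the inactive X chromosome, where mutant replicate 2 had 9 and the wild-type lungs 7 and 23. The Y-linked helicase gene Ddx3y stood at 56 in mutant replicate 1, at 3769 in mutant replicate 2, and at 2328 and 2197 in the wild type. Kdm5d, also on the Y chromosome, stood at 17, 977, 829 and 858 in the same order.

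In all, 440 genes passed the test between the genotypes, of which 271 were higher and 169 lower in the mutant. Among the genes that rose were targets of glucocorticoid signalling, immediate early genes and the secreted mucin gene Muc5b. Among those that fell were Wnt5a, Wnt7a and Rspo2, cardiac muscle genes and B-cell genes. Of the 440 genes, 376 differed by at least 1 on the log2 scale, 234 upward and 142 downward, and 14 lay on the X or Y chromosome. The test was limma with a mean-variance trend on log2(value + 1) over 18436 genes with a mean of at least 10, with 2 lungs per genotype and Benjamini-Hochberg adjustment. Both mutant lungs lay beyond both wild-type lungs, on either side, in 9702 of the 18436 tested genes. A chance share of 33.3% holds only for exchangeable libraries, and the wild-type lungs were closer to each other than the mutant lungs. The number is therefore no measure of an excess over chance. The number of calls depended on single lungs: limma gave 2385 without mutant replicate 1, the lung with high Xist, and 0 without mutant replicate 2 (5249 genes at an unadjusted p under 0.05), without wild-type replicate 1 (917) or without wild-type replicate 2 (1133). It was also 0 with no filter on low values (4876 at an unadjusted p under 0.05) and 72 without the trend.

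The largest increase was that of Fam107a (ENSMUSG00000021750, chromosome 14, positions 8296274 to 8318023), a stress-responsive actin-associated protein. Its normalized counts were 758 and 599 in the mutant and 26 and 22 in the wild type, a log2 fold change of 4.76 with a standard error of 0.22 (adjusted p = 0.00415). Zbtb16, a zinc finger transcription factor (chromosome 9, positions 48654311 to 48835945), reached 3519 and 4578 in the mutant against 129 and 202, a log2 fold change of 4.63 with a standard error of 0.25. The organic anion transporter gene Slco1a4 had a log2 fold change of 4.71 with a larger standard error of 0.63, from wild-type values of only 6 and 2. Galnt15, an enzyme that starts mucin-type O-glycosylation, rose by 3.89 on the log2 scale, with 1112 and 2763 against 123 and 112. Igfbp3, a binding protein for insulin-like growth factors, rose by 3.26, from 454 and 499 to 4102 and 5099, and Pappa, a protease that cleaves such binding proteins, rose by 3.21. The activin antagonist Fst (3.29), the ferritin receptor Scara5 (3.35), the protease inhibitor Serpina3n (3.27) and apolipoprotein D, Apod (3.21), were higher as well. The remaining genes of the 14 with the largest increases were Kcnt1 (3.80), a potassium channel, Mchr1 (3.69), a receptor for melanin-concentrating hormone, the phospholipase gene Pla1a (3.30) and Cbs (3.23), which makes cystathionine.

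Among the genes that fell, the atypical cadherin Fat3 (ENSMUSG00000074505, chromosome 9, positions 15910205 to 16378231) changed most. It had 15 and 9 normalized counts in the mutant and 272 and 196 in the wild type, a log2 fold change of -4.20 with a standard error of 0.34 (adjusted p = 0.00973). The fatty acid transporter gene Slc27a6 fell from 2983 and 2697 to 351 and 172, a log2 fold change of -3.52. Shisa2, which retains FGF and WNT receptors in the endoplasmic reticulum, had 58 and 47 against 627 and 649, or -3.59. The phosphatase gene Ptpn5 had a log2 fold change of -3.96. Meox2, a mesenchymal homeobox gene, fell by 2.47, with 545 and 218 against 2013 and 1833, and Olfml3, a secreted matrix protein gene, fell by 2.24. Esm1, an endothelial proteoglycan gene, fell by 2.50, and the peptidase gene Phex by 2.66. Tdrd5 (-2.54), Prss35 (-2.45), Frrs1l (-2.39), Plekha6 (-2.35) and Slitrk6 (-2.18) made up the rest of the 14 besides Rspo2. Without mutant replicate 1, Apod (adjusted p = 0.0575) and Esm1 (0.0711) no longer passed.

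**Figure D1:**
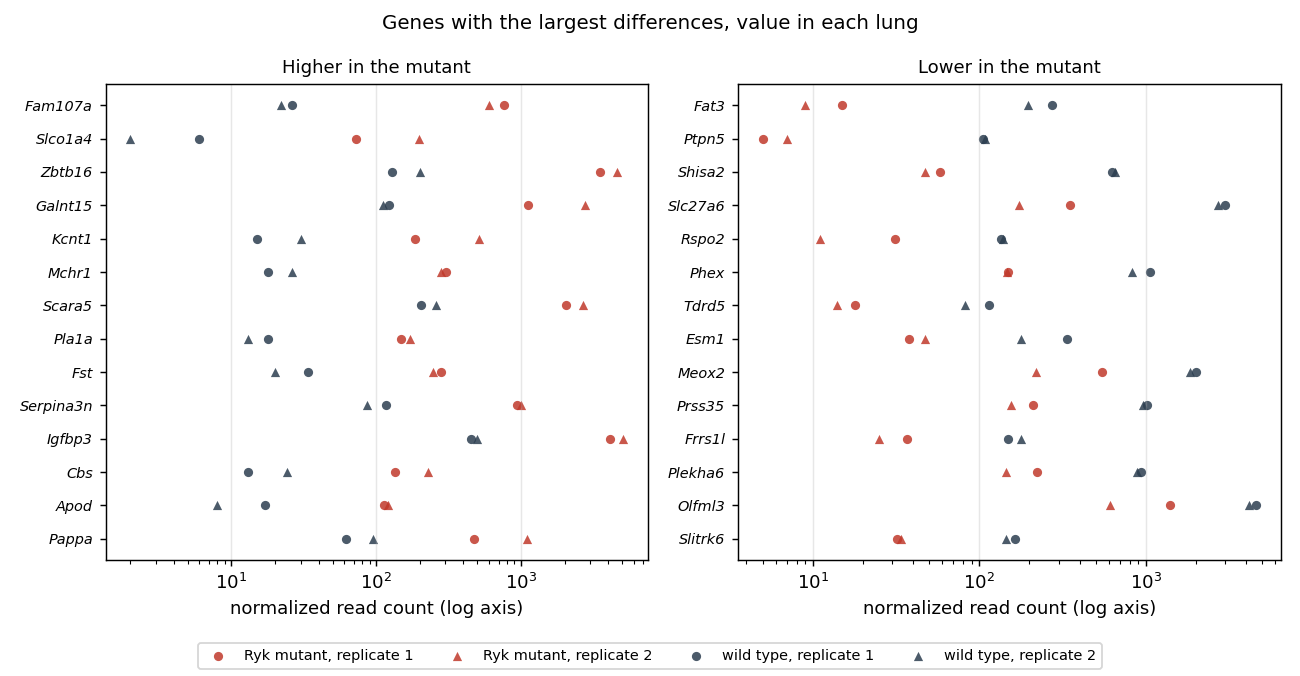
Normalized read count of the 14 genes with the largest increase (left) and the 14 with the largest decrease (right) in each lung, on a log axis. Red marks are mutant lungs and dark marks wild-type lungs, with circles for replicate 1 and triangles for replicate 2, and for every gene shown both mutant lungs lie beyond both wild-type lungs.

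Glucocorticoid-responsive and circadian genes were higher in both mutant lungs as a list, which had the smallest camera p of the 39 lists. Of its 24 measured genes, 11 rose and none fell, and 13 did not pass. Adjusted over the list alone, 18 were higher and 3 lower. Besides Zbtb16, the glucocorticoid receptor co-chaperone Fkbp5 rose by 2.92, from 474 and 626 normalized counts to 3969 and 4268. The cell cycle inhibitor Cdkn1a rose by 2.72 and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 2.09. The standard errors of these 3 genes were 0.175, 0.165 and 0.138. The median log2 fold change of the list was 1.05, at 0.98 in mutant replicate 1, which had high Xist, and 1.02 in mutant replicate 2. The difference between the wild-type lungs had a median of -0.10. The list passed in camera with a preset inter-gene correlation (adjusted p = 1.29e-11) but not with an estimated correlation (adjusted p = 0.386).

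Immediate early genes were higher in the mutant, with 4 of 23 measured genes passing and a list median of 0.89. The genes were Zfp36, which promotes mRNA decay (1.80), Dusp1, a MAP kinase phosphatase (1.5), and the transcription factor genes Klf6 (1.05) and Jun (0.89). Dusp1 did not pass after quantile normalization (adjusted p = 0.0570). Adjusted over the list alone, 9 genes were higher. The median was 0.34 in mutant replicate 1 and 1.07 in mutant replicate 2. Camera gave an adjusted p of 1.42e-06 (adjusted p = 0.558 with an estimated correlation). Of 25 hypoxia and glycolysis genes, 2 rose. Hexokinase 2, Hk2, was at 447 and 565 against 147 and 121, a log2 fold change of 1.91, and the mitophagy receptor Bnip3 was at 2241 and 3076 against 754 and 743, or 1.81. P4ha2 (0.90, adjusted p = 0.0534) and Ndrg1 (1.34, adjusted p = 0.0598) did not pass. Adjusted over the list alone, 7 genes were higher and 1 lower. The list median was 0.18 (camera, adjusted p = 0.00799, and adjusted p = 0.558 with an estimated correlation), and the list did not pass without mutant replicate 1 (adjusted p = 0.183). Of the 50-base sequences of Bnip3 transcripts, 47.2% also occur in transcripts of other genes.

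Of 31 measured genes for ligands, receptors and secreted modulators, 3 fell and none rose. Wnt5a (chromosome 14, positions 28504750 to 28527447), a ligand that mostly signals without beta-catenin, had 481 and 399 normalized counts against 1188 and 1116, a log2 fold change of -1.39 with a standard error of 0.157. The epithelial ligand gene Wnt7a had 103 and 86 against 278 and 279 (-1.56, standard error 0.192), and Rspo2, which amplifies WNT signalling, had 31 and 11 against 135 and 138 (-2.81, standard error 0.474). Wnt2, a mesenchymal ligand, was at 413 and 193 against 1132 and 1003 and did not pass (adjusted p = 0.0551). Adjusted over the list alone, 7 were lower and 1 was higher. The list median was -0.24 (camera, adjusted p = 0.0393, and adjusted p = 0.727 with an estimated correlation). It was -0.01 in mutant replicate 1 and -0.51 in mutant replicate 2, and the list did not pass without mutant replicate 2 (adjusted p = 0.438) or without wild-type replicate 2 (0.0907). Rspo2 did not pass after quantile normalization (adjusted p = 0.0570).

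Targets of canonical WNT signalling were also lower, with 2 of 29 measured genes passing, 9 lower when adjusted over the list alone, and a median of -0.41. The secreted WNT inhibitor gene Wif1 had 35 and 61 normalized counts against 175 and 171, a log2 fold change of -1.88 with a standard error of 0.306. Bmp4, a signalling ligand of the distal lung, had 382 and 291 against 736 and 682, or -1.09, with a standard error of 0.183. Notum (-1.52, adjusted p = 0.0553) and Wisp1 (-1.66, adjusted p = 0.0609) did not pass, and neither did Axin2, a widely used reporter of the pathway, at 693 and 947 against 727 and 731 (0.15, adjusted p = 0.693). Axin2 was named after its values were seen. Camera gave the list an adjusted p of 0.000942 (adjusted p = 0.558 with an estimated correlation). Of 20 planar cell polarity genes none passed, and the list median was -0.02 (camera, adjusted p = 0.985).

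The airway secretory genes did not move as a group. Of 18 measured goblet and mucous cell genes, 1 passed. Muc5b, a gel-forming mucin gene of the airway (ENSMUSG00000066108, chromosome 7, positions 141839070 to 141873084), rose from 50 and 47 normalized counts to 247 and 567, a log2 fold change of 2.92 with a standard error of 0.391 (limma, adjusted p = 0.0270). Muc5ac, the other main airway mucin gene, named after its values were seen, had 26 and 46 against 81 and 49 (-0.85, adjusted p = 0.298). Reg3g (1.40), Pigr (1.73) and Bpifb1 (0.97) did not pass, with adjusted p of 0.146, 0.196 and 0.199. The list median was -0.27 and its mean 0.13 (camera, adjusted p = 0.934), and adjusted over the list alone the count was again 1. None of 22 club cell genes passed, and adjusted over the list alone 2 were higher and 1 lower. Upk3a had 93 and 103 against 198 and 267 (-1.22, adjusted p = 0.0552), Retnlg 488 and 594 against 307 and 311 (0.80, adjusted p = 0.0760), and Scgb3a1 and Cyp4b1 had log2 fold changes of 0.78 and 0.64 (adjusted p = 0.0895 and 0.170). The club cell secretory protein gene Scgb1a1, also named after its values were seen, had 38846 and 35648 against 42922 and 46415 (adjusted p = 0.530). The club cell list had a camera adjusted p of 0.309. Of 24 NOTCH pathway genes, 1 passed. The ligand gene Dll4 fell from 876 and 839 to 481 and 383, a log2 fold change of -1.0. Notch2 (0.68), Jag2 (0.65) and Pofut1 (-0.54) did not pass, with adjusted p of 0.0713, 0.0912 and 0.134. The NOTCH list had a camera adjusted p of 0.832, and adjusted over the list alone 2 genes were higher and 1 lower.

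**Figure D2:**
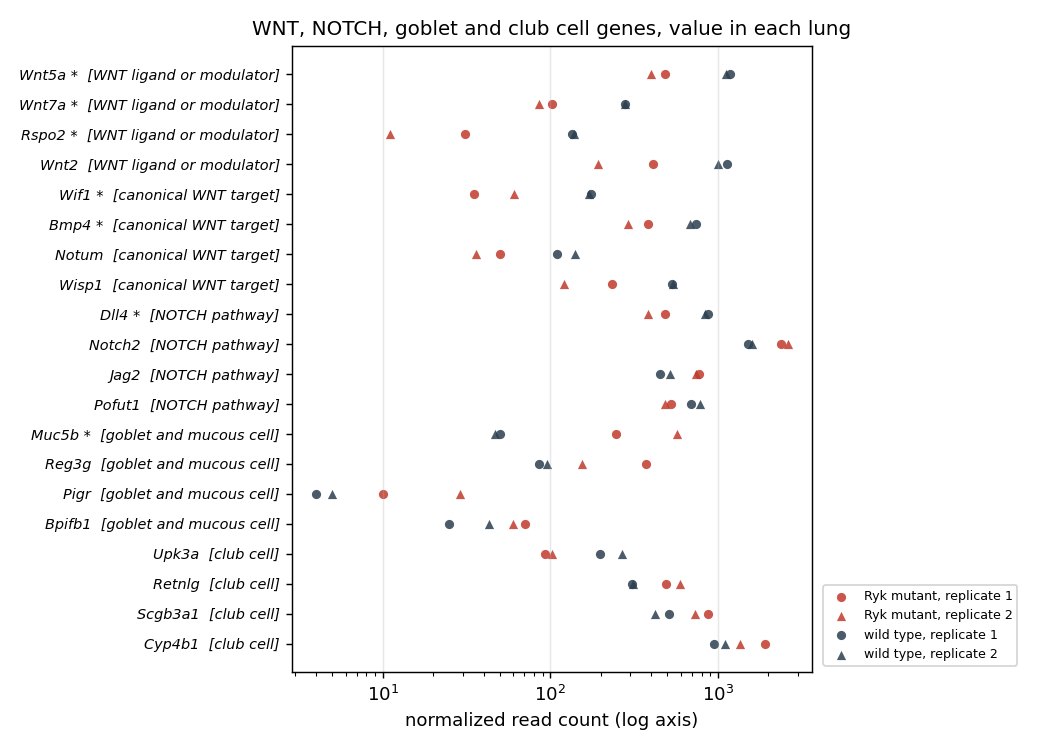
Normalized read count in each lung, on a log axis, of up to 4 genes with the smallest p from the WNT, NOTCH, goblet and club cell lists; an asterisk marks an adjusted p under 0.05. Red marks are mutant and dark marks wild-type lungs, and Muc5b stands at 247 and 567 in the mutant lungs against 50 and 47.

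Alveolar type 2 cell genes were lower as a list, with 2 of 30 measured genes passing and a median of -0.41. The chemokine gene Cxcl15 fell from 34355 and 30055 to 12794 and 13009, a log2 fold change of -1.32 with a standard error of 0.182, and Bex2 fell by 1.43. Of the 50-base sequences of Bex2 transcripts, 22.2% are shared with other genes. Lamp3 (-0.67, adjusted p = 0.110) and Etv5 (-1.38, adjusted p = 0.136) did not pass, nor did the surfactant protein gene Sftpc, named after its values were seen, at 179120 and 135559 against 220945 and 200581 (adjusted p = 0.507). Adjusted over the list alone 2 genes were lower, and camera gave an adjusted p of 0.00252 (adjusted p = 0.558 with an estimated correlation). Myofibroblast and elastic fibre genes had a median of -0.54 over 21 genes (camera, adjusted p = 0.000181, and adjusted p = 0.558 with an estimated correlation). In this list the matrix gene Fbln1 fell by 1.17 and the growth factor receptor gene Pdgfra rose by 1.45, from 1363 and 1682 to 3260 and 5235. Fbln5 (-0.89) and the elastin crosslinking enzyme gene Loxl1 (-0.86) did not pass, with adjusted p of 0.0932 and 0.0944. Adjusted over the list alone, 11 genes were lower and 2 higher. Pdgfra did not pass after quantile normalization (adjusted p = 0.0611).

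Fibroblast and collagen genes went both ways, with 2 of 28 higher and 4 lower. Inmt, a methyltransferase gene of lung fibroblasts, rose from 2811 and 3549 to 9450 and 10338 (1.65), and the lipase gene Lpl rose by 0.99. Besides Meox2, the lipid droplet gene Plin2 (-0.98), the proteoglycan gene Lum (-1.85) and the growth factor gene Igf1 (-0.92) fell. Lpl and Igf1 were named after their values were seen, and Lpl did not pass after quantile normalization (adjusted p = 0.0653). The list median was -0.34 (camera, adjusted p = 0.0172, and adjusted p = 0.558 with an estimated correlation), and adjusted over the list alone 2 were higher and 10 lower. The list did not pass without mutant replicate 2 (adjusted p = 0.129). Without mutant replicate 1, Lum (adjusted p = 0.0521) and Igf1 (0.0527) did not pass.

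The lymphocyte, macrophage and interferon-response lists were lower in the mutant. Of 26 listed genes of B and T lymphocytes and thymus, 10 were measured and 3 fell. Most T-cell genes of this list lay below the filter on low values, so it is mainly a reading of B cells. Ms4a1, which encodes CD20, had 37 and 32 normalized counts against 158 and 144 (-2.10, standard error 0.231). The immunoglobulin constant genes Igkc and Ighm fell by 1.82 and 1.43, and Cd79a (-1.78, adjusted p = 0.0587) did not pass. Over the list the median was -1.06 (camera, adjusted p = 9.2e-05), and 6 genes were lower when adjusted over the list alone. With an estimated correlation this list did not pass (adjusted p = 0.558). Among 24 macrophage and monocyte genes, Siglecf, a surface lectin of alveolar macrophages and eosinophils, had 3 and 2 against 36 and 30 (-3.29), and Ms4a7 fell by 1.69. Fabp4, a fatty acid binding protein that capillary endothelium and adipocytes also make, rose by 1.72, and the integrin gene Itgax (-2.79, adjusted p = 0.0556) did not pass. Macrophage and monocyte genes had a median of -0.54 (camera, adjusted p = 9.03e-05), and did not pass with an estimated correlation (adjusted p = 0.558). In this list 11 were lower and 1 higher when adjusted over the list alone. Interferon-response genes had a median of -0.62 over 27 genes, of which 26 were below 0 and 2 fell, Iigp1 by 1.26 and Ifit1 by 1.23. Isg15 (-0.92, adjusted p = 0.0629) did not pass. Camera gave this list an adjusted p of 1.16e-08, which was 0.558 with an estimated correlation, and 9 genes were lower when adjusted over the list alone.

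Cardiac muscle genes were lower in both mutant lungs. All 17 measured genes were below 0 and 6 fell. The atrial light chain genes Myl7 and Myl4 had log2 fold changes of -1.62 and -1.28, with Myl7 at 394 and 460 normalized counts against 1333 and 1288. Tnnc1 (-1.35), Mybpc3 (-1.45), Ttn (-1.08) and Csrp3 (-1.05), all of the sarcomere, fell too. Ttn and Csrp3 were named after their values were seen, and Csrp3 did not pass after quantile normalization (adjusted p = 0.0608). The list median was -0.95, at -0.93 in mutant replicate 1 and -1.10 in mutant replicate 2 (camera, adjusted p = 1.62e-09, and adjusted p = 0.386 with an estimated correlation), and 11 genes were lower when adjusted over the list alone. Of 15 liver genes only 5 reached the minimum level, at low values, and none passed. With no filter on low values camera gave the liver list an adjusted p of 4.43e-05 with the preset correlation. Apoa1 had 21 and 29 against 6 and 10 (1.55), Alb 51 and 26 against 16 and 11 (1.39), and Apob and Rbp4 had log2 fold changes of 1.32 and 0.43, with adjusted p of 0.136, 0.170, 0.263 and 0.295. The liver list had a median of 1.32 (camera, adjusted p = 0.0160, and adjusted p = 0.558 with an estimated correlation), 2 genes were higher when adjusted over the list alone, and it did not pass without mutant replicate 1 (adjusted p = 0.298).

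**Figure D3:**
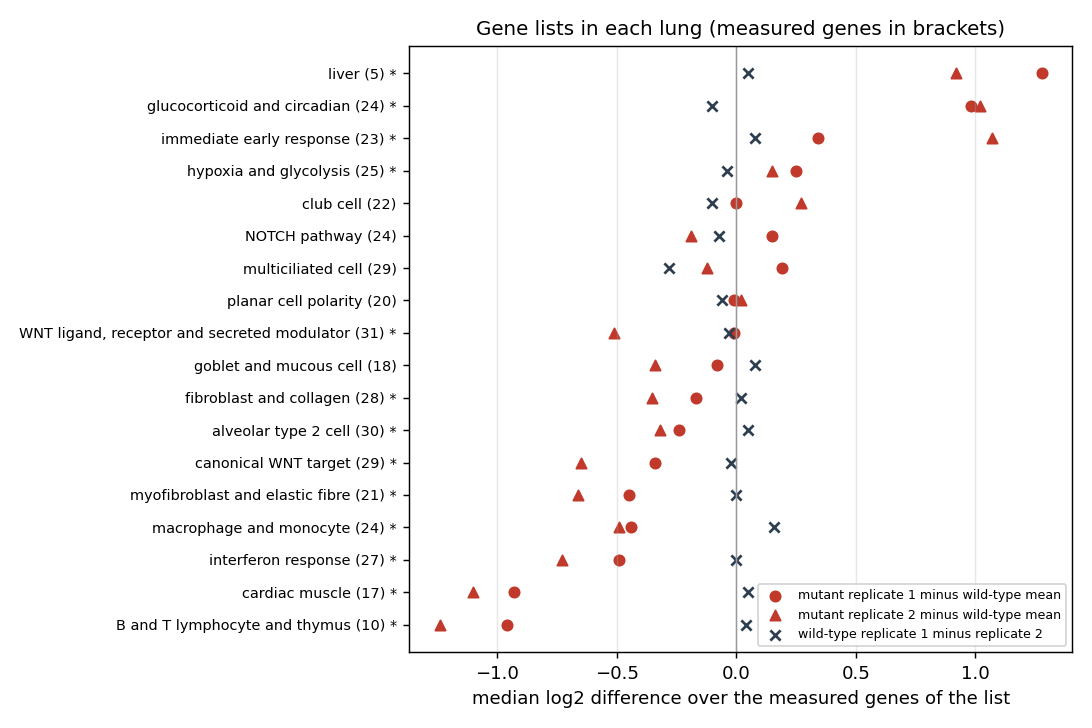
Median log2 difference over the measured genes of each list, for mutant replicate 1 (red circles) and mutant replicate 2 (red triangles) against the wild-type mean and for the wild-type lungs against each other (crosses), with the number of measured genes in brackets. An asterisk marks a camera adjusted p under 0.05 with the preset correlation, and the cardiac muscle list lies at -0.93 and -1.10 where the wild-type lungs differ by 0.05.

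The other 26 lists did not pass in camera, with adjusted p from 0.0643 for erythroid cells and blood to 0.985 for planar cell polarity. They included multiciliated, basal, neuroendocrine and alveolar type 1 cells, smooth muscle, mesothelium, mast cells, cholesterol synthesis, mitochondrially encoded mRNA and histone mRNA. Of these 26 lists, 15 had no gene past the threshold. In the other 11, 14 genes passed, among them Muc5b and Dll4, and the remaining ones were named after their values were seen. Cebpd, a transcription factor gene induced by glucocorticoids and cytokines, rose from 523 and 455 to 2097 and 6090 normalized counts (2.87), and the homeobox gene Irx1 of the lung epithelium rose by 0.89. The gap junction gene Gja5 of arterial endothelium fell from 1853 and 1833 to 624 and 522 (-1.69). Herpud1 of the unfolded protein response rose by 1.56 and the neutrophil collagenase gene Mmp8 by 1.54. The replication gene Mcm5 (-1.03) and the cartilage matrix gene Matn4 (-0.99) fell. In the type 2 inflammation list the eosinophil-associated ribonuclease genes Ear1 (-1.59) and Ear2 (-1.34) fell. The eosinophil granule genes Epx and Prg2 of this list lay below the filter on low values. Epx had 2 and 1 normalized counts in the mutant against 0 and 0, and Prg2 had 3 and 0 against 2 and 2. The falls are therefore not read as a loss of eosinophils. In the lymphatic endothelium list the chemokine genes Ccl21a (-1.03) and Ccl21b (-0.92) fell. Ear1, Ear2, Ccl21a and Ccl21b have near-identical copies. Of the 50-base sequences, 57.4%, 41.5% and 71.6% are shared for Ear1, Ear2 and Ccl21a, and the whole transcript for Ccl21b. Each value is therefore uncertain for the single gene. Nefm passed at 24 and 14 normalized counts against 1 and 1, close to the lower limit of the measurement. After quantile normalization Irx1 (adjusted p = 0.0554), Mcm5 (0.0574) and Nefm (0.0527) did not pass, nor did Irx1 without mutant replicate 1 (0.0511) or Nefm with a pseudocount of 8 (0.0635). The mutant lungs went opposite ways in several of these lists, with medians in mutant replicates 1 and 2 of 0.51 and -0.33 for proliferation, 0.18 and -0.61 for smooth muscle and -0.57 and 0.34 for mesothelium. In 11 of the 26 lists the median, the mean and the direction of the test differed in sign, and no direction is given for them.

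Of 6843 annotation terms tested with camera, 4 passed upward and 10 downward with the preset correlation, and 0 passed with an estimated one, where the smallest-p terms named here had adjusted p = 0.999. The upward terms that could be paired with a name were pre-autophagosomal structure (26 genes, median 0.42, adjusted p = 0.0169), circadian regulation of gene expression (46 genes, of which 6 rose, adjusted p = 0.0252) and negative regulation of TOR signaling (32 genes, of which 4 rose, adjusted p = 0.0277). Response to glucocorticoid, with 8 of 49 genes higher and 1 lower, did not pass (adjusted p = 0.0512). The downward terms with the smallest p were cytokine activity (89 genes, of which 7 fell and 2 rose), antigen processing and presentation (61 genes, median -0.31) and the mitochondrial ribosome (67 genes, median -0.23), each with an adjusted p of 0.0169. Chemokine activity (16 genes, median -1.0, adjusted p = 0.0348) and lateral sprouting from an epithelium (12 genes, of which 3 fell, adjusted p = 0.0455) also passed downward.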

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

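The restriction to protein-coding genes (433 calls) was the alternative chosen after the data were seen. The 440 calls stayed within 1.5 times of that number with pseudocounts of 0.5 and 8, a mean of at least 50, TMM, median-of-ratios and quantile scaling and in protein-coding genes, at 419 to 469. The median ratios of the deposited values were already 1.0005 to 1.0049, so median-of-ratios scaling is close to the main fit. With no filter on low values limma called 0 genes, 0 higher and 0 lower (4876 at an unadjusted p under 0.05). Without the trend it called 72, 46 higher and 26 lower. Same-numbered libraries did not deviate together (correlation -0.058), but with 2 libraries per genotype this single value cannot exclude a pairing of the mice. The fit with the replicate block called 766 genes, 437 higher and 329 lower. Leaving out libraries in turn gave 0 to 2385 calls, 0 to 1199 higher and 0 to 1186 lower: 2385 without mutant replicate 1, 413 of them among the 440, and 0 without each of the others. In these fits the lone library is assumed to vary like the other group. The cause of these changes was not tested. The 4 libraries allow 3 splits, too few for a share under 0.05; the real split gave 440 calls and the highest other split 0 (132 at an unadjusted p under 0.05). Ryk ranged from -0.198 to 0.126 and Axin2 from -0.073 to 0.377 over the libraries left out, both turning sign without mutant replicate 2. Of the 124 genes selected for naming besides Ryk, of which 90 passed, all 90 were lost without the filter and without each of mutant replicate 2, wild-type replicate 1 and wild-type replicate 2, 65 without the trend, 9 with quantile scaling, 6 without mutant replicate 1 and 1, Nefm, with a pseudocount of 8. None of the 13 passing lists did so with an estimated correlation: adjusted p was 0.386 for the glucocorticoid and cardiac lists, 0.727 for WNT ligands and modulators and 0.558 for the other lists. With fry the glucocorticoid, cardiac (both 0.0444) and hypoxia (0.0475) lists passed. The others did not: interferon and fibroblast (0.140), immediate early (0.253), macrophage (0.128), lymphocyte (0.143), myofibroblast (0.217), canonical WNT target (0.207), alveolar type 2 (0.226), liver (0.147) and WNT ligands (0.260). The WNT ligand list also missed the threshold with no filter (0.0503), a mean of at least 50 (0.0519) and no trend (0.0583). Lists that passed only in an alternative were erythroid (0.0478), cholesterol synthesis (0.0343) and mast cell (0.0279) genes with no filter, and cholesterol synthesis (0.0270) and blood endothelium (0.0229) genes with quantile scaling. Over the libraries left out, adjusted p ran from 0.00246 to 0.183 for hypoxia, 0.000814 to 0.298 for liver, 0.00804 to 0.129 for fibroblasts, 0.0172 to 0.438 for WNT ligands, 0.0186 to 0.266 for erythroid genes, 0.000707 to 0.646 for cholesterol synthesis, 1.47e-05 to 0.293 for smooth muscle, 0.0275 to 0.337 for mitochondrially encoded mRNA, 0.00351 to 0.786 for blood endothelium, 0.0243 to 0.550 for histone mRNA and 0.00804 to 0.900 for proliferation. The smooth muscle, blood endothelium and proliferation lists passed, downward, only without mutant replicate 1 among these fits, and pointed upward without mutant replicate 2 (0.0829, 0.786 and 0.114). The planned edgeR and DESeq2 fits were not run, since the table holds rounded normalized values from which counts are not uniquely recovered.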

Other observations

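Other genes with large differences, all named after their values were seen and outside the lists fixed beforehand, included Klf15, Ddit4, Sesn1 and Glul. Klf15, a transcription factor of fasting metabolism, rose from 313 and 337 normalized counts to 2657 and 2846 (3.08, standard error 0.138). Ddit4 and Sesn1, both inhibitors of the TOR kinase, rose by 2.67 and 1.79. Glul, which makes glutamine, rose from 3315 and 3351 to 18764 and 15398 (2.35). Mutant replicate 1 was the only lung with high Xist and low Y-linked values, so sex differed within the mutant group and between the groups.

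The test on the sex of mutant replicate 1 was chosen after the result was seen, and Arntl, Cry1, Dbp, Tef and Chst2 were named after their values were seen. The first pattern is the rise of glucocorticoid-responsive genes: 9 of the 12 such members of the fixed list rose, with a median of 2.05. The female-like pattern of mutant replicate 1 does not account for it, since the median in mutant replicate 2, whose Y-linked values were like those of the wild type, was 2.15, where the wild-type lungs differed by -0.08. Reduced feeding stays open, because neither of the lists examined can decide it. The 23 PPAR-alpha and fatty acid oxidation genes, predicted to rise, had a median of -0.23 with none past the threshold. Of them 3 were above 0 (camera, unadjusted p = 0.0018, downward, and 0.135 with an estimated correlation). These values met the bound set beforehand against reduced feeding. By contrast, 8 of 21 FoxO and nutrient-limitation genes rose and none fell, with a median of 0.76. The bound set beforehand on the first list was too narrow to exclude reduced feeding, since that list covers a single arm of the response and left out targets it shares with the glucocorticoid list. The second list was written after the largest changes were seen, Klf15 and Ddit4 among them, so its rise is no independent test. A shift of clock phase may contribute and also stays open: the arm with Arntl (median 1.00, Arntl and Cry1 rising by 1.08 and 1.07) and the arm with Dbp (median -0.16) differed by 1.16, but members of the second arm went both ways, with Dbp at -1.57 and Tef at 0.89, neither of which passed. Sampling time and the genotype itself stay open and were not tested.

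The second pattern is the lower level of cardiac muscle genes. If the mutant libraries held less cardiac muscle, from heart tissue or from the muscle sleeve of the pulmonary veins, its genes would fall together. All 13 cardiac genes with a wild-type mean of at least 100 were lower, from -1.62 to -0.42, with an SD of 0.37 around a mean of -1.0. A smaller share of that tissue could give such a joint fall. The SD exceeded the standard errors of the cardiac genes named above, such as 0.149 for Myl7 and 0.208 for Mybpc3. Those genes had the smallest p of the list, which favours small errors, so whether the falls were uniform stays open. The test cannot tell a smaller share from lower expression within the same tissue. Whether such a share would come from dissection or from the genotype cannot be read from these libraries.

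The third pattern concerns genes close to Ryk on chromosome 9, where a mutation bred onto another background could carry neighbouring variants along. Within 10 Mb of Ryk, 2 of 224 tested genes passed (0.893%), among them Chst2, which was lower, against 410 of 16715 genes on the other autosomes (2.45%; one-sided Fisher's exact p = 0.974). The calls were thus not concentrated around the mutated locus. The share covers effects on neighbouring genes only, so it cannot tell whether a variant linked to Ryk changed genes elsewhere.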
